A study of Arabidopsis thaliana with 14 samples.

How the data were processed

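Whole embryos of Arabidopsis thaliana Col-0 were isolated at 7 stages with 2 biological replicates each, per the labels. Total RNA was extracted with the RNAqueous-Micro kit, messenger RNA was amplified as antisense RNA with the MessageAmp kit and libraries were made with the TruSeq RNA kit, version 1, per the labels' protocols. That library kit does not mark strand. The submitters' processing notes name CASAVA, Trimmomatic, FastQC, STAR, HTSeq and DESeq2 and the genome build TAIR10. Their roles, order and versions are not given in the sources used here. The deposited table holds a normalised signal per gene and library that the authors derived from read counts, and how it was scaled is not given in the sources used here. Size factors of DESeq2 had been assumed before the data were examined. The values showed another scaling, since each library's column summed to 20000000 over all its entries, those without a gene identifier included. Every value was a whole multiple of the smallest positive value of its library within 0.001 reads, so whole reads were recovered for 100% of values. The table has 25517 entries, of which 103 carry no gene identifier and 25414 are named genes. Of the named genes 1976 were at 0 in every library and 24932 matched a locus of the reference annotation, build TAIR10.1, which gave symbols and positions. The libraries held 6078186 to 30803336 reads, of which 5403798 to 27500092 lay in named genes. The value of 1 read, 3 reads as a floor for a count of 0, and 95% counting intervals were computed per library.

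The comparisons, tests, gene lists and naming rule were chosen before the data were examined. Genes with a value of 10 or more in at least 2 libraries were tested (18744 genes, with 6670 not tested). Values were log2-transformed after adding 4 and fitted with limma 3.58.1 in R 4.3.3, with stage as the only term over all 14 libraries and a trend in the prior variance. The fit had 7 residual degrees of freedom and 7.81 prior degrees of freedom, so each stage's spread was taken to be like that of the others. The 6 consecutive comparisons, zygote against mature, and an F test over all stages were adjusted after Benjamini and Hochberg (BH) at 0.05. Changes are later minus earlier stage. No library was left out and no column of the table was unused.

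Gene lists were embryo patterning, maturation regulators, seed storage proteins, oil body proteins, LEA and desiccation proteins, small heat shock proteins, fatty acid synthesis, oil assembly, photosynthesis, cell division, DNA methylation and silencing, auxin synthesis and transport, abscisic acid metabolism, and egg cell and zygote. Reference genes were 1 more list. Endosperm markers, seed coat markers, and pollen and synergid markers stood for other tissues of the seed. These 18 lists held 355 members, of which 302 were in the table, 50 were absent from it and were not analysed here, and 3 were left out because locus and symbol disagreed. Of the seed storage list 8 of 13 genes were analysed, without the 2S albumin genes SESA1 to SESA5. The cell division list kept 19 of 37. No gene was in more than 1 list. Cytosolic ribosomal proteins, 22 genes taken by their description, made the list number 19. Each list was tested with camera at a correlation of 0.01 in the 7 comparisons, 133 tests adjusted together (BH), and 54 passed. With an estimated correlation 9 passed. For each of the 54 the list's mean relative to the other genes lay on the called side in both libraries of 1 stage against both of the other. Peak stages were tested with a one-sided Fisher's exact test for each list and stage, 133 tests adjusted together (BH) over the genes past the F test.

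Genes were named by rule, namely the 5 largest rises and 5 largest falls per consecutive comparison and 10 of each from zygote to mature. They had to have an adjusted p under 0.05, a mean of 100 or more in the higher stage and no overlap between the libraries of the compared stages. Up to 4 members per list and comparison were allowed as examples. Read sharing was measured as the share of 50-base words of a transcript found in another gene. Of 78 rule genes 1 shared more than 20% and 9 overlapped another gene, and of 324 list members 8 shared more than 20% and 77 overlapped another gene.

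Alternatives were pseudocounts of 1 and 16, no filter, a filter at 50, equal totals over named genes, upper-quartile scaling, quantile normalization, limma array weights, the replicate number as a block, a fit of the compared stages alone with 2 residual degrees of freedom, and each library left out in turn. A library alone in its stage was then assumed to vary like the other stages. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 (Wald test) were run on the recovered reads, and lists were also tested with fry. Centring log2 values on each library's median was chosen after seeing the data. Reads were thinned to 5403798 in named genes per library to compare gene detection at equal depth. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

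The tests were run first on simulated counts for zygote to octant over 18315 genes, with 50 changed at each fold size. limma recovered 0% at 2-fold, 46% at 4-fold, 92% at 8-fold and 98% at 16-fold, with 10 false among 128 calls. edgeR recovered 2%, 48%, 96% and 98% with 7 false among 129, and DESeq2 10%, 60%, 92% and 98% with 21 among 151. camera called the raised list and 0 of 20 unchanged lists, which leaves correlated genes untested.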

Results

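RNA was sequenced from whole embryos of the Arabidopsis thaliana reference strain Col-0 at 7 stages, with 2 biological replicate libraries per stage and 14 libraries in all, as an atlas of gene expression. The stages ran from the zygote, the fertilised egg cell, through the octant, globular, heart, torpedo and bent embryo to the mature embryo of the ripe seed. The libraries held 20625372 and 13563668 reads at the zygote stage, 25846263 and 8880532 at octant, 6078186 and 15715299 at globular, and 13247056 and 19982767 at heart. They held 6097762 and 30803336 at torpedo, 17798620 and 12068569 at bent, and 12783748 and 20444185 at the mature stage. All expression values below are normalised read counts in reads per 20000000, given as mean ± SD of n = 2 libraries. Each named change was tested with limma, p-values were adjusted after Benjamini and Hochberg, and for every gene said to have risen or fallen both libraries of the higher stage lay above both of the lower stage.

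Genes at a value of 10 or more numbered 14908 ± 252 in zygote, 16506 ± 157 in octant, 14767 ± 5.66 in globular and 15494.5 ± 19.1 in heart libraries. The number was 15576.5 ± 135 in torpedo, 15127.5 ± 325 in bent and 13055 ± 523 in mature libraries. No test was made on these numbers, and an exact test of 2 libraries against 2 reaches no p below 0.333. The correlation across genes between the libraries of a stage ranged from 0.949 to 0.980 (genes are not independent replicates). Of the 18744 genes tested, 18193 (97.1%) differed among the 7 stages (limma F test, adjusted p under 0.05).

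**Figure D1:**
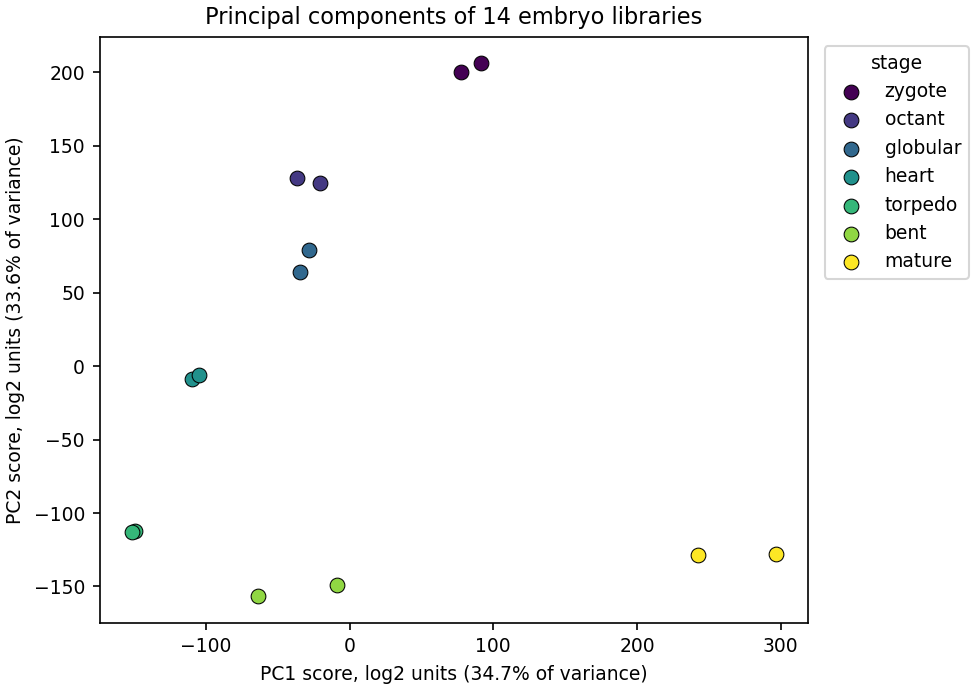
Position of the 14 libraries on the first and second principal components of log2(value + 4) over the genes tested, one point per library, coloured by stage. The components carry 34.7% and 33.6% of the variance, and the 2 libraries of each stage lie beside each other.

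Gene positions are those of the reference build TAIR10.1, and the submitters' notes name TAIR10. The libraries do not mark strand, so values are uncertain for genes that overlap another annotated gene, which among those named or drawn in these texts are OLEO1, FIE, KAN1, MYB5, CKX2, MCM7, EXPA21, BCCP2, NF-YB6, OLEO5, PSAH1, PLT3, LHCB1.5, ACP1, HSFA9, AAO3, HSP101, AT4G25890, RAB18, AUR1, EC1.1, NUC-L1 and AT5G47350. Values are also uncertain where transcripts share more than 10% of their 50-base words with a copy elsewhere, which among all named or drawn holds for HSD1 (100% shared) and LHCB1.5 (17.3%).

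Zygote and octant embryos were compared to see which RNAs changed over the first divisions. Among genes of late embryogenesis abundant (LEA) proteins, which protect cells during drying, EM1 (AT3G51810) fell from 939 ± 280.0 to 7.88 ± 11.1, and LEA48 (AT5G44310) fell from 552 ± 48.2 to 19.2 ± 11.2. The storage protein genes CRB (AT1G03880) and VCL22 (AT2G28490) fell from 2002 ± 166 to 286 ± 16.5 and from 586 ± 26.4 to 26.2 ± 10.8. The oleosin gene OLEO1 (AT4G25140), whose product coats oil bodies, fell from 2186 ± 96.9 to 179.8 ± 73.7. In the other direction MET1 (AT5G49160), the maintenance DNA methyltransferase, rose from 45.0 ± 11.5 to 1299 ± 73.5, and the embryo regulator BBM (AT5G17430) rose from 9.06 ± 5.96 to 299.5 ± 105. Markers of the seed coat, a maternal tissue, were present at both stages, with BAN (AT1G61720) of proanthocyanidin synthesis at 2514 ± 1209 and 13199 ± 454.

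Among the LEA and desiccation proteins 16 of 23 tested genes fell and 1 rose (16 and 1 adjusted within the list, 21 and 1 median-centred). The LEA list averaged -3.25 in log2 relative to the other genes (camera adjusted p = 8.91e-11, and adjusted p = 0.0996 with an estimated correlation). Among the seed storage proteins 7 of 8 tested genes fell and 0 rose (8 and 0 adjusted within the list, 8 and 0 median-centred). The storage protein list averaged -3.32 in log2 relative to the other genes (camera adjusted p = 2.02e-06, and adjusted p = 0.103 with an estimated correlation). In the oil body list 6 of 10 tested genes fell and 0 rose (7 and 0 adjusted within the list, 8 and 0 median-centred). The oil body list averaged -2.57 in log2 relative to the other genes (camera adjusted p = 8.30e-05, and adjusted p = 0.0442 with an estimated correlation). Of the small heat shock proteins, chaperones that hold unfolded proteins, 6 of 12 tested genes fell and 1 rose (6 and 1 adjusted within the list, 8 and 0 median-centred). The small heat shock list averaged -1.86 in log2 relative to the other genes (camera adjusted p = 0.00513, and adjusted p = 0.116 with an estimated correlation). HSP17.6B (AT2G29500) fell from 188 ± 21.3 to 9.08 ± 6.27 and HSP15.7 (AT5G37670) fell from 102 ± 1.68 to 8.34 ± 4.13. Of the photosynthesis genes 7 of 45 tested genes fell and 4 rose (4 and 2 adjusted within the list, 18 and 1 median-centred). The photosynthesis list averaged -1.15 in log2 relative to the other genes (camera adjusted p = 0.00113, and adjusted p = 0.665 with an estimated correlation). PSAO (AT1G08380) of photosystem I fell from 2018 ± 251 to 234 ± 25.5. The seed coat list, measured beside these, had a camera adjusted p of 0.995.

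In the DNA methylation and silencing list 18 of 23 tested genes rose and 1 fell (18 and 1 adjusted within the list, 12 and 3 median-centred). The methylation list averaged 1.39 in log2 relative to the other genes (camera adjusted p = 0.00984, and adjusted p = 0.542 with an estimated correlation). FIE (AT3G20740) of the Polycomb complex rose from 19.8 ± 11.6 to 610.4 ± 0.148 and NRPD1B (AT2G40030) of RNA polymerase V rose from 9.54 ± 5.27 to 235 ± 72.6. In the cell division list 17 of 19 tested genes rose and 0 fell (17 and 0 adjusted within the list, 8 and 0 median-centred). The cell division list averaged 1.43 in log2 relative to the other genes (camera adjusted p = 0.0249, and adjusted p = 0.665 with an estimated correlation). The cell division call was lost with a pseudocount of 1 (camera adjusted p = 0.0688). The replication licensing gene CDT1A (AT2G31270) rose from 193 ± 6.42 to 1907 ± 513. The cell division call was lost without octant replicate 2 (camera adjusted p = 0.0632, and 0.00554 to 0.0688 over other settings at a correlation of 0.01).

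Of the embryo patterning genes 14 of 32 tested genes rose and 3 fell (12 and 3 adjusted within the list), but after median-centring 4 rose and 9 fell, and the list did not pass (camera adjusted p = 0.837). PHB (AT2G34710), which specifies upper organ faces, rose from 56.9 ± 3.25 to 947 ± 119, and KAN1 (AT5G16560), its counterpart for lower faces, fell from 173 ± 25.8 to 6.86 ± 0.147. Of the maturation regulators 7 of 17 tested genes rose and 4 fell (7 and 4 adjusted within the list), which became 5 and 7 with upper-quartile scaling, 3 and 6 with quantile normalization and 3 and 9 after median-centring. The median was -0.40, the mean 0.13 and the camera direction down (adjusted p = 0.117). In the auxin list 8 of 16 tested genes rose and 3 fell (8 and 4 adjusted within the list), turning to 4 and 6 after median-centring, with a median of 1.34, a mean of 0.83 and a camera direction of down (camera adjusted p = 0.978). The auxin exporter gene PIN3 (AT1G70940) fell from 5370.5 ± 943 to 464 ± 109. Of the abscisic acid genes 2 of 10 tested genes rose and 2 fell (2 and 2 adjusted within the list, 0 and 4 median-centred, camera adjusted p = 0.149). In the list of fatty acid synthesis 12 of 23 tested genes rose and 1 fell (12 and 1 adjusted within the list, 4 and 4 median-centred), and in that of oil assembly 8 of 11 tested genes rose and 0 fell (8 and 0 adjusted within the list, 7 and 2 median-centred), with camera adjusted p-values of 0.852 and 0.0585. Neither of 2 egg cell genes changed past the test (0 adjusted within the list), and the egg cell gene EC1.5 (AT5G64720) stood at 1237 ± 542 and 1134 ± 46.4.

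Of the endosperm markers 5 of 13 tested genes rose and 1 fell (3 and 0 adjusted within the list), turning to 0 and 2 after median-centring (camera adjusted p = 0.830). Of the seed coat markers 4 of 9 tested genes rose and 0 fell (4 and 0 adjusted within the list), turning to 2 and 3 after median-centring, and the proton pump gene AHA10 (AT1G17260) rose from 29.9 ± 16.2 to 875 ± 139. Of the reference genes 6 of 10 tested genes rose and 0 fell (6 and 0 adjusted within the list), and 4 rose and 4 fell after median-centring (camera adjusted p = 0.697). Of the genes picked by size of change, HB4 (AT2G44910), a homeodomain leucine zipper gene (chromosome 2, 18517656 to 18519731), rose from 9.33 ± 11.8 to 873 ± 294 (log2 change 6.36, SE 0.76, adjusted p = 1.41e-05, limma). AT3G50030 had 0 reads in zygote and 229 ± 103 in octant libraries, at least 62.5-fold higher. AT3G45160, a putative membrane lipoprotein gene (chromosome 3, 16533428 to 16534265), fell to 2 reads in octant, a ratio of 1999 (553 to 16516). AT4G37080 fell from 5510.5 ± 448 to 19.4 ± 4.43 (log2 change -7.89, SE 0.73, adjusted p = 2.94e-06, limma).

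From zygote to octant 10839 genes passed the test, 8381 up and 2458 down, against 3966 up and 5519 down with median-centred values. The median log2 change of all genes was 0.92, so list means are given relative to the other genes and the balance of rises and falls depends on the scaling. List tests were not matched on gene length. Intervals (95%) and floors (3 reads) at few reads cover counting error only.

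Octant and globular embryos were compared to see which RNAs changed as the first tissues form. The organ boundary regulator CUC1 (AT3G15170) rose from 3 reads in octant to 667 ± 295 in globular, a ratio of 332 (113 to 1617). WOX5 (AT3G11260), which maintains root stem cells, had 0 reads in octant and 185 ± 18.1 in globular libraries, at least 40.7-fold higher. The maturation regulator ABI3 (AT3G24650) rose from 45.8 ± 7.45 to 728 ± 75.6, and YUC1 (AT4G32540) of auxin synthesis rose from 3.10 ± 4.38 to 150.3 ± 35.8. The seed coat marker BAN fell from 13199 ± 454 to 304 ± 64.0, AHA10 fell from 875 ± 139 to 7.85 ± 7.51 and INO (AT1G23420) of the outer integument fell from 596 ± 70.7 to 10.3 ± 5.25.

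In the embryo patterning list 11 of 32 tested genes rose and 5 fell (11 and 5 adjusted within the list, 15 and 1 median-centred). The patterning list averaged 1.76 in log2 relative to the other genes (camera adjusted p = 4.39e-06, and adjusted p = 0.216 with an estimated correlation). Of the LEA and desiccation proteins 11 of 23 tested genes rose and 1 fell (13 and 1 adjusted within the list, 16 and 1 median-centred). Members of the LEA list averaged 1.93 relative to the other genes (camera adjusted p = 2.21e-08, and adjusted p = 0.129 with an estimated correlation). LEA76 (AT3G15670) rose from 21.002 ± 4.22 to 256 ± 21.8. Of the oil body proteins 3 of 10 tested genes rose and 0 fell (3 and 0 adjusted within the list, 5 and 0 median-centred). Members of the oil body list averaged 1.31 relative to the other genes (camera adjusted p = 0.0106, and adjusted p = 0.116 with an estimated correlation). In the list of cytosolic ribosomal proteins 8 of 18 tested genes rose and 3 fell (8 and 3 adjusted within the list, 12 and 1 median-centred). The ribosomal list averaged 1.27 in log2 relative to the other genes (camera adjusted p = 0.000506, and adjusted p = 0.216 with an estimated correlation). Of the seed coat markers 7 of 9 tested genes fell and 0 rose (7 and 0 adjusted within the list, 6 and 1 median-centred). The seed coat list averaged -2.50 in log2 relative to the other genes (camera adjusted p = 0.00781, and adjusted p = 0.111 with an estimated correlation). MYB5 (AT3G13540) of seed coat development fell from 817 ± 56.3 to 23.9 ± 5.84. Of the pollen and synergid markers 2 of 4 tested genes fell and 0 rose (2 and 0 adjusted within the list, camera adjusted p = 0.149), with the pectin methylesterase gene VGDH1 (AT2G47030) falling from 514 ± 21.3 to 13.6 ± 0.592.

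Another 4 lists passed camera with few members past the test or with members going both ways. Of the maturation regulators 4 of 17 tested genes rose and 4 fell (4 and 4 adjusted within the list, 6 and 3 median-centred). The maturation list averaged 0.89 in log2 relative to the other genes (camera adjusted p = 0.0490, and adjusted p = 0.480 with an estimated correlation). The maturation call was lost with a pseudocount of 1 (camera adjusted p = 0.0688), with no filter (0.0664), with the stricter filter (0.0521), with upper-quartile scaling (0.122), with quantile normalization (0.138), with edgeR (0.0799), with DESeq2 (0.0667) and after median-centring (0.102). ABI5 (AT2G36270) fell from 281 ± 118 to 10.51 ± 13.1. That call was lost without zygote replicate 1 (adjusted p = 0.0513), zygote replicate 2 (0.0504), octant replicate 1 (0.0584), octant replicate 2 (0.0507) and globular replicate 2 (0.123). It was also lost without heart replicate 1 (camera adjusted p = 0.0511), torpedo replicate 1 (0.0523) and torpedo replicate 2 (0.0522), with values of 0.0247 to 0.138 over other settings at a correlation of 0.01. Of the photosynthesis genes 4 of 45 tested genes fell and 1 rose (4 and 0 adjusted within the list), turning to 5 rises and 4 falls with upper-quartile scaling, 5 and 3 with quantile normalization and 9 and 4 after median-centring. The list's median of 0.03, mean of -0.14 and camera direction of up differed in sign (camera adjusted p = 0.0204, and adjusted p = 0.758 with an estimated correlation). The photosynthesis call was lost with upper-quartile scaling (camera adjusted p = 0.0662), with quantile normalization (0.134), with edgeR (0.0540), with DESeq2 (0.135) and after median-centring (0.146). This call was lost without octant replicate 2 (camera adjusted p = 0.0664) and without globular replicate 1 (0.0672), with values of 0.00754 to 0.146 over other settings at a correlation of 0.01. In the cell division list 1 of 19 tested genes rose and 0 fell (0 and 0 adjusted within the list, 7 and 0 median-centred) (camera adjusted p = 0.0211, and adjusted p = 0.665 with an estimated correlation). The cell division call was lost with quantile normalization (camera adjusted p = 0.0594). Of single libraries, it was lost without octant replicate 1 (adjusted p = 0.0684) and without globular replicate 1 (0.140), with values of 0.00494 to 0.140 over other settings at a correlation of 0.01. In the list of fatty acid synthesis 1 of 23 tested genes rose and 0 fell (0 and 0 adjusted within the list, 4 and 0 median-centred) (camera adjusted p = 0.0184, and adjusted p = 0.665 with an estimated correlation). The fatty acid call was lost with quantile normalization (camera adjusted p = 0.166).

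In the auxin list 5 of 16 tested genes rose and 5 fell (6 and 5 adjusted within the list, 6 and 2 median-centred, camera adjusted p = 0.0855), with YUC6 (AT5G25620) falling from 364 ± 70.9 to 13.8 ± 5.62. Of the endosperm markers 3 of 13 tested genes rose and 3 fell (4 and 3 adjusted within the list, 5 and 2 median-centred, camera adjusted p = 0.193), and MYB118 (AT3G27785) rose from 16.7 ± 5.03 to 175 ± 36.6 where AGL35 (AT5G26630) fell from 103 ± 34.5 to 9.13 ± 5.71. In the DNA methylation list 5 of 23 tested genes fell and 1 rose (4 and 0 adjusted within the list), turning to 1 and 3 after median-centring (camera adjusted p = 0.948). Of the abscisic acid genes 3 of 10 tested genes fell and 0 rose (2 and 0 adjusted within the list, 2 and 1 median-centred, camera adjusted p = 0.880), and CYP707A3 (AT5G45340), which breaks the hormone down, fell from 101 ± 32.9 to 7.11 ± 0.746. Of the genes picked by size of change, the sugar transporter gene SWEET9 (AT2G39060) (chromosome 2, 16306491 to 16308362) rose from 1 read in octant to 844 ± 291, a ratio of 1307 (234 to 51671). ASL5 (AT2G30130), a lateral organ boundaries gene, rose from 3.41 ± 1.54 to 855 ± 302 (log2 change 6.83, SE 0.65, adjusted p = 2.87e-06, limma). The subtilase gene AT4G21630 (chromosome 4, 11492248 to 11495538) fell from 2874 ± 207 to 4.56 ± 2.85 (log2 change -8.43, SE 0.59, adjusted p = 4.78e-07, limma), and the lectin gene JAL23 (AT2G39330) fell from 2547 ± 443 to 5.84 ± 1.05.

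From octant to globular 7210 genes passed the test, 1315 up and 5895 down, against 3239 up and 2845 down with median-centred values, and the median log2 change of all genes was -0.63. Without octant replicate 2 the count was 4463, and in a fit of these 2 stages alone it was 3794.

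Globular and heart embryos were compared to see which RNAs changed as the cotyledons emerge. PSBO2 (AT3G50820) of the oxygen-evolving complex of photosynthesis rose from 42.2 ± 14.7 to 1939 ± 825. The organ polarity gene YAB3 (AT4G00180) rose from 2.55 ± 3.60 to 499 ± 10.15, and the organ growth gene JAG (AT1G68480) rose from 3.18 ± 4.50 to 445 ± 106. The storage protein gene CRB fell from 298 ± 61.998 to 8.04 ± 5.71 and CRC (AT4G28520) fell from 209.6 ± 31.2 to 9.79 ± 1.104. DRN (AT1G12980), which acts in early cotyledon founding, fell from 1252 ± 137 to 36.6 ± 3.69.

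Of the photosynthesis genes 24 of 45 tested genes rose and 0 fell (26 and 1 adjusted within the list, 18 and 1 median-centred). Members of the photosynthesis list averaged 1.75 relative to the other genes (camera adjusted p = 0.000433, and adjusted p = 0.665 with an estimated correlation). Of the seed storage proteins 5 of 8 tested genes fell and 1 rose (5 and 1 adjusted within the list). Members of the storage protein list averaged -2.15 relative to the other genes (camera adjusted p = 0.000295, and adjusted p = 0.169 with an estimated correlation). The exception VCL41 (AT4G36700) rose from 47.4 ± 16.7 to 741 ± 154. Of the LEA and desiccation proteins 11 of 23 tested genes fell and 0 rose (13 and 0 adjusted within the list, 18 and 0 median-centred). For the LEA list the mean was -2.13 relative to the other genes (camera adjusted p = 4.95e-10, and adjusted p = 0.107 with an estimated correlation). EM1 fell from 121 ± 33.1 to 4.01 ± 1.403 where EM6 (AT2G40170) fell from 89.4 ± 13.1 to 6.02 ± 0.0240. Of the cytosolic ribosomal proteins 12 of 18 tested genes fell and 1 rose (13 and 2 adjusted within the list, 14 and 1 median-centred). Members of the ribosomal list averaged -2.11 relative to the other genes (camera adjusted p = 3.06e-09, and adjusted p = 0.0588 with an estimated correlation). AT1G53950 fell from 528 ± 239 to 9.78 ± 3.15. Of the endosperm markers 5 of 13 tested genes fell and 1 rose (5 and 1 adjusted within the list, 8 and 1 median-centred). The endosperm list averaged -1.39 in log2 relative to the other genes (camera adjusted p = 0.000914, and adjusted p = 0.0588 with an estimated correlation). The endosperm call was lost with DESeq2 (camera adjusted p = 0.0808). CKX2 (AT2G19500) of cytokinin breakdown fell from 359 ± 88.5 to 16.3 ± 8.10. In the egg cell list 1 of 2 tested genes fell and 0 rose (1 and 0 adjusted within the list) (camera adjusted p = 0.0381, and adjusted p = 0.353 with an estimated correlation). The egg cell call was lost with a pseudocount of 1 (camera adjusted p = 0.0550), with no filter (0.191), with upper-quartile scaling (0.0924), with quantile normalization (0.0828), in the fit of the compared stages alone (0.210), with edgeR (0.0981), with DESeq2 (0.0528) and after median-centring (0.0810). The egg cell call was lost without globular replicate 1 (camera adjusted p = 0.147) and without heart replicate 1 (0.0917), with values of 0.00773 to 0.210 over other settings at a correlation of 0.01, and EC1.5 stood at 414 ± 303 and 28.3 ± 3.79. Of the seed coat markers 1 of 9 tested genes fell and 0 rose (1 and 0 adjusted within the list, 3 and 0 median-centred, camera adjusted p = 0.156).

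In the DNA methylation list 14 of 23 tested genes rose and 2 fell (14 and 2 adjusted within the list, 4 and 2 median-centred, camera adjusted p = 0.0503), and CMT2 (AT4G19020), a plant-specific methyltransferase, rose from 33.0 ± 0.130 to 303 ± 42.7. In the cell division list 5 of 19 tested genes rose and 0 fell (4 and 0 adjusted within the list, 1 and 1 median-centred, camera adjusted p = 0.456), and the helicase gene MCM7 (AT4G02060) rose from 268 ± 35.2 to 1333 ± 132. Of the embryo patterning genes 7 of 32 tested genes rose and 4 fell (7 and 4 adjusted within the list), turning to 5 and 6 with quantile normalization and to 3 and 7 after median-centring (camera adjusted p = 0.453). Of the oil body proteins 5 of 10 tested genes rose and 2 fell (6 and 2 adjusted within the list, 2 and 2 median-centred, camera adjusted p = 0.513), and OLEO3 (AT5G51210) rose from 223 ± 54.2 to 3862 ± 1005. Of the pollen and synergid markers 4 of 4 tested genes rose and 0 fell (4 and 0 adjusted within the list, 1 and 0 median-centred, camera adjusted p = 0.0839). Of the genes picked by size of change, HB33 (AT1G75240), a zinc finger homeodomain gene (chromosome 1, 28241011 to 28242795), rose from 5.20 ± 1.95 to 1258 ± 250.5 (log2 change 7.10, SE 0.38, adjusted p = 1.02e-07, limma). LSU1 (AT3G49580), a marker of low sulfur (chromosome 3, 18374908 to 18375940), fell from 8076 ± 273 to 1 read in heart, a ratio of 13276 (2382 to 524437). The expansin gene EXPA21 (AT5G39260), of a family that loosens cell walls, fell from 9312 ± 3769.9 to 13.03 ± 9.88 (log2 change -9.17, SE 0.55, adjusted p = 1.02e-07, limma).

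From globular to heart 6476 genes passed the test, 5183 up and 1293 down, against 1842 up and 3227 down with median-centred values, and the median log2 change of all genes was 0.59. By gene length the longest of 4 equal groups changed by a median log2 of 1.25 and the shortest by -0.06. Without heart replicate 1 the count was 3886, and in a fit of these 2 stages alone it was 897.

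Heart and torpedo embryos were compared to see which RNAs changed as the cotyledons lengthen. The oleosin gene OLEO1 rose from 319 ± 27.8 to 29549 ± 4699, CRA1 (AT5G44120), a cruciferin storage protein, rose from 16.8 ± 0.288 to 2551 ± 1072, and BCCP2 (AT5G15530) of fatty acid synthesis rose from 1304 ± 8.74 to 17332 ± 3755. LEC1 (AT1G21970), a master regulator of embryo development, fell from 13844 ± 6818 to 1301 ± 581, and its close relative NF-YB6 (AT5G47670) rose from 185 ± 7.12 to 8841 ± 5072. RNAs of the photosynthesis list made up 1.28% ± 0.0980 of a library at heart and 5.90% ± 1.08 at torpedo (n = 2).

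Of the seed storage proteins 8 of 8 tested genes rose and 0 fell (8 and 0 adjusted within the list). For the storage protein list the mean was 5.08 relative to the other genes (camera adjusted p = 2.04e-10, and adjusted p = 0.0442 with an estimated correlation). Of the oil body proteins 7 of 10 tested genes rose and 0 fell (7 and 0 adjusted within the list). For the oil body list the mean was 3.12 relative to the other genes (camera adjusted p = 6.00e-08, and adjusted p = 0.0173 with an estimated correlation). OLEO5 (AT3G01570) rose from 139 ± 49.5 to 19626 ± 1756. Of the photosynthesis genes 31 of 45 tested genes rose and 0 fell (33 and 0 adjusted within the list, 28 and 0 median-centred). For the photosynthesis list the mean was 2.48 relative to the other genes (camera adjusted p = 2.63e-10, and adjusted p = 0.480 with an estimated correlation). PSAH1 (AT3G16140) of photosystem I rose from 233 ± 0.492 to 5951 ± 596. In the list of fatty acid synthesis 11 of 23 tested genes rose and 0 fell (14 and 0 adjusted within the list, 8 and 0 median-centred). The fatty acid list averaged 1.58 in log2 relative to the other genes (camera adjusted p = 0.000134, and adjusted p = 0.560 with an estimated correlation). In the oil assembly list 8 of 11 tested genes rose and 0 fell (8 and 1 adjusted within the list, 7 and 1 median-centred). The oil assembly list averaged 1.94 in log2 relative to the other genes (camera adjusted p = 0.000433, and adjusted p = 0.149 with an estimated correlation). The desaturase gene FAD2 (AT3G12120) rose from 11722 ± 2597 to 67202 ± 13155. Of the maturation regulators 7 of 17 tested genes rose and 1 fell (9 and 1 adjusted within the list, 5 and 1 median-centred). Members of the maturation list averaged 1.201 relative to the other genes (camera adjusted p = 0.0137, and adjusted p = 0.404 with an estimated correlation). Of the LEA and desiccation proteins 8 of 23 tested genes rose and 0 fell (9 and 0 adjusted within the list, 4 and 1 median-centred). The LEA list averaged 0.96 in log2 relative to the other genes (camera adjusted p = 0.0109, and adjusted p = 0.480 with an estimated correlation). The call was lost without torpedo replicate 2 (adjusted p = 0.136, and 0.000204 to 0.136 over other settings at a correlation of 0.01).

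Of the endosperm markers 6 of 13 tested genes fell and 1 rose (6 and 1 adjusted within the list). Members of the endosperm list averaged -1.14 relative to the other genes (camera adjusted p = 0.00844, and adjusted p = 0.111 with an estimated correlation). The endosperm call was lost with the stricter filter (camera adjusted p = 0.0720) and with quantile normalization (0.0728). MYB118 fell from 330.2 ± 22.8 to 43.1 ± 17.85 where ALE1 (AT1G62340) rose from 9.04 ± 4.29 to 113 ± 25.7. Of the seed coat markers 2 of 9 tested genes fell and 1 rose (3 and 1 adjusted within the list, 4 and 1 median-centred, camera adjusted p = 0.190), and of the pollen and synergid markers 2 of 4 tested genes fell and 0 rose (2 and 0 adjusted within the list, camera adjusted p = 0.0662). In the embryo patterning list 4 of 32 tested genes rose and 6 fell (4 and 7 adjusted within the list, 3 and 10 median-centred, camera adjusted p = 0.0955), with PLT3 (AT5G10510) of the root rising from 174 ± 8.89 to 1648 ± 499 and DRNL (AT1G24590) falling from 276 ± 137 to 19.3 ± 0.601. In the DNA methylation list 4 of 23 tested genes rose and 5 fell (6 and 6 adjusted within the list, 2 and 8 median-centred, camera adjusted p = 0.330), and the Argonaute gene AGO5 (AT2G27880) fell from 246 ± 8.60 to 23.46 ± 9.98. The cell division list had 1 rise and 1 fall (1 and 1 adjusted within the list, camera adjusted p = 0.731). By size of change, FAE1 (AT4G34520), which lengthens the fatty acids of seed oil (chromosome 4, 16494205 to 16495842), rose from 2 reads in heart to 4554 ± 799.9, a ratio of 4098 (1134 to 33842). The vicilin-like gene PAP85 (AT3G22640) rose from 3 reads to 2056 ± 529, a ratio of 1278 (437 to 6197). GASA1 (AT1G75750) (chromosome 1, 28441501 to 28442435) fell from 1806 ± 357 to 9.43 ± 8.70 (log2 change -7.23, SE 0.53, adjusted p = 9.45e-07, limma), and MLP328 (AT2G01520) fell from 536 ± 179.9 to 0 reads, at least 91.0-fold lower.

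From heart to torpedo 4765 genes passed the test, 3046 up and 1719 down, against 1965 up and 3132 down with median-centred values, and the median log2 change of all genes was 0.19. The count was 2709 without heart replicate 1, 2873 without heart replicate 2, 2554 without torpedo replicate 1 and 2599 without torpedo replicate 2.

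Torpedo and bent embryos were compared to see which RNAs changed at the start of seed filling. The cruciferin storage protein genes CRC and CRB rose, CRC from 297 ± 217 to 699998.5 ± 438355 and CRB from 158 ± 33.5 to 269389 ± 37723. Storage protein RNAs went from 0.268% ± 0.142 to 11.6% ± 3.71 of a library and oil body protein RNAs from 0.943% ± 0.0604 to 9.92% ± 0.435 (n = 2). DOG1 (AT5G45830), which sets seed dormancy, rose from 11.4 ± 7.01 to 1927 ± 57.8. The DNA replication gene PCNA1 (AT1G07370) fell from 3105 ± 12.996 to 102 ± 59.5 and MCM4 (AT2G16440) fell from 1548 ± 645 to 66.9 ± 50.04, and LEC1 fell from 1301 ± 581 to 23.4 ± 5.01.

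Of the seed storage proteins 8 of 8 tested genes rose and 0 fell (8 and 0 adjusted within the list). The storage protein list averaged 7.95 in log2 relative to the other genes (camera adjusted p = 2.97e-21, and adjusted p = 0.0173 with an estimated correlation). Of the oil body proteins 9 of 10 tested genes rose and 0 fell (9 and 1 adjusted within the list). The oil body list averaged 5.05 in log2 relative to the other genes (camera adjusted p = 6.36e-16, and adjusted p = 0.00603 with an estimated correlation). The caleosin gene CLO1 (AT4G26740) rose from 1997 ± 158 to 67108 ± 1772. Of the LEA and desiccation proteins 12 of 23 tested genes rose and 1 fell (13 and 2 adjusted within the list, 14 and 1 median-centred). Members of the LEA list averaged 3.23 relative to the other genes (camera adjusted p = 3.88e-14, and adjusted p = 0.0588 with an estimated correlation). The peroxiredoxin gene PER1 (AT1G48130) rose from 84.5 ± 12.8 to 17159 ± 1375 and ECP63 (AT2G36640) from 25.4 ± 8.12 to 7595 ± 227. In the cell division list 19 of 19 tested genes fell and 0 rose (19 and 0 adjusted within the list). Members of the cell division list averaged -3.00 relative to the other genes (camera adjusted p = 5.47e-10, and adjusted p = 0.353 with an estimated correlation). After median-centring 18 fell. In the DNA methylation list 9 of 23 tested genes fell and 0 rose (10 and 0 adjusted within the list, 4 and 0 median-centred). Members of the methylation list averaged -0.80 relative to the other genes (camera adjusted p = 0.0198, and adjusted p = 0.564 with an estimated correlation). The methylation call was lost in the fit of the compared stages alone (camera adjusted p = 0.0582). CMT3 (AT1G69770) fell from 1227 ± 251 to 87.0 ± 59.7 and MET1 from 1685 ± 115 to 169.6 ± 43.0. This call was lost without torpedo replicate 1 (camera adjusted p = 0.0604) and without bent replicate 2 (0.0819), with values of 0.00434 to 0.0819 over other settings at a correlation of 0.01. Of the embryo patterning genes 13 of 32 tested genes fell and 0 rose (18 and 0 adjusted within the list). Members of the patterning list averaged -0.75 relative to the other genes (camera adjusted p = 0.0109, and adjusted p = 0.480 with an estimated correlation). The patterning call was lost in the fit of the compared stages alone (camera adjusted p = 0.149). After median-centring 3 fell and 1 rose. That call was lost without bent replicate 2 (camera adjusted p = 0.0819, and 0.00150 to 0.149 over other settings at a correlation of 0.01). Of the cytosolic ribosomal proteins 9 of 18 tested genes fell and 0 rose (13 and 0 adjusted within the list, 2 and 0 median-centred). For the ribosomal list the mean was -0.73 relative to the other genes (camera adjusted p = 0.0182, and adjusted p = 0.420 with an estimated correlation). The ribosomal call was lost in the fit of the compared stages alone (camera adjusted p = 0.163). The call was lost without bent replicate 1 (adjusted p = 0.0727, and 0.00667 to 0.163 over other settings at a correlation of 0.01).

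Of the maturation regulators 3 of 17 tested genes rose and 3 fell (4 and 4 adjusted within the list, 4 and 3 median-centred, camera adjusted p = 0.445), and LEC2 (AT1G28300) fell from 177 ± 8.41 to 10.6 ± 0.915. In the oil assembly list 2 of 11 tested genes rose and 0 fell (2 and 0 adjusted within the list, 4 and 0 median-centred, camera adjusted p = 0.101), with a median of -0.38 and a mean of 0.39. FAD3 (AT2G29980), which makes linolenic acid, rose from 7154 ± 8.08 to 127799 ± 86269.8. Of the photosynthesis genes 4 of 45 tested genes fell and 0 rose (2 and 0 adjusted within the list, 2 and 0 median-centred, camera adjusted p = 0.2498). In the auxin list 5 of 16 tested genes fell and 0 rose (7 and 0 adjusted within the list, 2 and 0 median-centred, camera adjusted p = 0.163), and YUC1 fell from 128 ± 4.15 to 5.86 ± 1.25. Of the endosperm markers 2 of 13 tested genes fell and 1 rose (2 and 1 adjusted within the list, camera adjusted p = 0.466), and of the seed coat markers 1 of 9 tested genes fell and 0 rose (1 and 0 adjusted within the list), turning to 1 fall and 2 rises after median-centring (camera adjusted p = 0.456). Of the genes picked by size of change, CRC (chromosome 4, 14087556 to 14089796) had a log2 change of 11.24, SE 0.51, adjusted p = 9.21e-09 with limma. The dehydrin gene LEA (AT2G21490) rose from 17.2 ± 15.1 to 20763 ± 1790.2 (log2 change 10.14, SE 0.62, adjusted p = 1.30e-07, limma), and the ethylene response gene ERF6 (AT4G17490) (chromosome 4, 9752824 to 9754161) fell from 850.2 ± 305 to 11.5 ± 9.20 (log2 change -5.88, SE 0.52, adjusted p = 3.06e-06, limma). AT1G50650, of a stigma-specific family, fell from 161 ± 22.4 to 0 reads, at least 38.7-fold lower. HSD1 (AT5G50600), a steroleosin gene, had values of 10.7 ± 15.2 and 13842 ± 1379.9, but its whole transcript is shared with AT5G50700.

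From torpedo to bent 5149 genes passed the test, 1023 up and 4126 down, against 1861 up and 1740 down with median-centred values, and the median log2 change of all genes was -0.54. The count was 2633 without torpedo replicate 1, 3381 without torpedo replicate 2 and 2515 without bent replicate 2, and limma on these 2 stages alone called 0 genes, where 5917 had an unadjusted p under 0.05 and on all libraries edgeR called 3202 and DESeq2 3605.

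Bent and mature embryos were compared to see which RNAs changed as the seed dries. LEA RNAs went from 0.420% ± 0.0958 to 12.5% ± 1.24 of a library (n = 2). M10 (AT2G41280) had 0 reads in bent and 176711 ± 51088 in mature libraries, at least 42363-fold higher, and EM6 rose from 9.41 ± 10.13 to 361729.7 ± 65599. The small heat shock protein gene HSP17.6A (AT5G12030) rose from 38.6 ± 22.8 to 119863.5 ± 16915. FAD3 fell from 127799 ± 86269.8 to 64.8 ± 60.6. WRI1 (AT3G54320), a regulator of oil synthesis, fell from 3624 ± 2121 to 49.7 ± 68.1, and LHCB1.5 (AT2G34420) of the light-harvesting antenna fell from 28780.2 ± 17537 to 158 ± 206. CYP707A2 (AT2G29090), which breaks down abscisic acid, rose from 20.14 ± 14.4 to 2305 ± 1544.

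Among the LEA and desiccation proteins 21 of 23 tested genes rose and 0 fell (21 and 1 adjusted within the list, 22 and 0 median-centred). For the LEA list the mean was 7.49 relative to the other genes (camera adjusted p = 4.89e-17, and adjusted p = 0.0442 with an estimated correlation). Among the small heat shock proteins 11 of 12 tested genes rose and 0 fell (11 and 0 adjusted within the list). Members of the small heat shock list averaged 6.91 relative to the other genes (camera adjusted p = 1.22e-09, and adjusted p = 0.0173 with an estimated correlation). HSP15.7 rose from 22.9 ± 4.21 to 3956 ± 1717. In the list of fatty acid synthesis 23 of 23 tested genes fell and 0 rose (23 and 0 adjusted within the list, 22 and 0 median-centred). Members of the fatty acid list averaged -5.41 relative to the other genes (camera adjusted p = 1.49e-08, and adjusted p = 0.432 with an estimated correlation). ACP1 (AT3G05020) fell from 24163 ± 6015 to 224 ± 268. Among the photosynthesis genes 44 of 45 tested genes fell and 0 rose (44 and 0 adjusted within the list). The photosynthesis list averaged -5.82 in log2 relative to the other genes (camera adjusted p = 4.59e-12, and adjusted p = 0.464 with an estimated correlation). In the oil assembly list 9 of 11 tested genes fell and 0 rose (9 and 0 adjusted within the list, 8 and 0 median-centred). Members of the oil assembly list averaged -3.69 relative to the other genes (camera adjusted p = 0.000359, and adjusted p = 0.148 with an estimated correlation). FAE1 fell from 30086 ± 4296 to 303 ± 105. In the cell division list 17 of 19 tested genes fell and 0 rose (17 and 0 adjusted within the list, 12 and 1 median-centred). For the cell division list the mean was -2.02 relative to the other genes (camera adjusted p = 0.00599, and adjusted p = 0.633 with an estimated correlation). The cell division call was lost in the fit of the compared stages alone (camera adjusted p = 0.331). Among the embryo patterning genes 23 of 32 tested genes fell and 1 rose (23 and 2 adjusted within the list). For the patterning list the mean was -1.34 relative to the other genes (camera adjusted p = 0.0109, and adjusted p = 0.480 with an estimated correlation). The patterning call was lost in the fit of the compared stages alone (camera adjusted p = 0.0618). After median-centring 13 fell and 5 rose. For DNA methylation 16 of 23 tested genes fell and 2 rose (16 and 2 adjusted within the list, 13 and 6 median-centred). For the methylation list the mean was -1.54 relative to the other genes (camera adjusted p = 0.0200, and adjusted p = 0.564 with an estimated correlation). The methylation call was lost in the fit of the compared stages alone (camera adjusted p = 0.130). AGO4 (AT2G27040) fell from 6278 ± 2988 to 204 ± 47.5.

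Among the maturation regulators 12 of 17 tested genes fell and 3 rose (12 and 3 adjusted within the list, 9 and 3 median-centred, camera adjusted p = 0.115). HSFA9 (AT5G54070), a heat shock factor of seeds, had 0 reads in bent and 1623 ± 176 in mature libraries, at least 389-fold higher. Among the seed storage proteins 6 of 8 tested genes fell and 0 rose (6 and 0 adjusted within the list, 4 and 1 median-centred, camera adjusted p = 0.0814), and VCL41 fell from 300944 ± 1071 to 3289 ± 742. Among the oil body proteins 7 of 10 tested genes fell and 2 rose (7 and 2 adjusted within the list, 6 and 3 median-centred, camera adjusted p = 0.190), and OLEO3 fell from 116995 ± 42148 to 1201 ± 106. Among the abscisic acid genes 4 of 10 tested genes rose and 3 fell (5 and 3 adjusted within the list, 7 and 2 median-centred, camera adjusted p = 0.190), and AAO3 (AT2G27150), which makes the hormone from its last precursor, rose from 35.9 ± 7.84 to 293 ± 47.9. Among the reference genes 5 of 10 tested genes fell and 1 rose (5 and 1 adjusted within the list), turning to 3 falls and 4 rises after median-centring (camera adjusted p = 0.597), and GAPC1 (AT3G04120) of glycolysis fell from 17331 ± 4791 to 516 ± 307. Among the endosperm markers 1 of 13 tested genes rose and 1 fell (0 and 0 adjusted within the list), with 8 rises after median-centring (camera adjusted p = 0.405), and of the seed coat markers 3 of 9 tested genes fell and 1 rose (2 and 1 adjusted within the list), turning to 2 falls and 4 rises after median-centring (camera adjusted p = 0.883). Of the genes picked by size of change, EM6 (chromosome 2, 16779552 to 16780368) had a log2 change of 14.95, SE 0.63, adjusted p = 6.32e-10 with limma. FAD3 (chromosome 2, 12781524 to 12785190) had a log2 change of -11.03, SE 0.60, adjusted p = 5.01e-09 with limma, and scpl17 (AT3G12203), a carboxypeptidase-like gene, fell from 20007 ± 5589 to 31.6 ± 20.3.

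From bent to mature 10941 genes passed the test, 3420 up and 7521 down, against 8199 up and 4111 down with median-centred values, and the median log2 change of all genes was -0.57. No single library moved this count by more than 1.5 times when left out.

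Zygote and mature embryos were compared as the first and last stages of the series. Every LEA gene tested rose, for example LEA76 from 242 ± 12.7 to 305936 ± 134973, and CLO1 of oil bodies rose from 389 ± 27.0 to 198851 ± 43631. LEC1 fell from 25809 ± 6017 to 5.38 ± 7.61, and WOX8 (AT5G45980), a regulator of the basal embryo lineage, fell from 549.6 ± 46.4 to 0 reads, at least 144-fold lower. The auxin exporter gene PIN3 fell from 5370.5 ± 943 to 1.96 ± 2.77, and EC1.5 fell from 1237 ± 542 to 0 reads, at least 324-fold lower. The seed coat marker BAN fell from 2514 ± 1209 to 2 reads, a ratio of 2235 (618 to 18459).

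Among the LEA and desiccation proteins 23 of 23 tested genes rose and 0 fell (23 and 0 adjusted within the list). The LEA list averaged 8.23 in log2 relative to the other genes (camera adjusted p = 2.36e-14, and adjusted p = 0.0588 with an estimated correlation). Among the oil body proteins 10 of 10 tested genes rose and 0 fell (10 and 0 adjusted within the list). Members of the oil body list averaged 5.95 relative to the other genes (camera adjusted p = 3.17e-06, and adjusted p = 0.0305 with an estimated correlation). Among the small heat shock proteins 10 of 12 tested genes rose and 0 fell (10 and 0 adjusted within the list). Their mean was 5.66 relative to the other genes (camera adjusted p = 7.46e-06, and adjusted p = 0.0442 with an estimated correlation). HSP101 (AT1G74310), in the list but not small, rose from 335 ± 43.3 to 37792 ± 9793. Among the seed storage proteins 7 of 8 tested genes rose and 0 fell (7 and 0 adjusted within the list). Members of the storage protein list averaged 6.18 relative to the other genes (camera adjusted p = 0.000158, and adjusted p = 0.158 with an estimated correlation). CRC rose from 463 ± 148 to 259254 ± 48448. Among the photosynthesis genes 32 of 45 tested genes fell and 2 rose (32 and 2 adjusted within the list, 29 and 2 median-centred). Members of the photosynthesis list averaged -2.79 relative to the other genes (camera adjusted p = 0.000134, and adjusted p = 0.652 with an estimated correlation). The photosynthesis call was lost in the fit of the compared stages alone (camera adjusted p = 0.219). PSAK (AT1G30380) fell from 2901 ± 216 to 73.5 ± 99.5. Among the cytosolic ribosomal proteins 14 of 18 tested genes fell and 1 rose (14 and 1 adjusted within the list, 13 and 1 median-centred). The ribosomal list averaged -3.61 in log2 relative to the other genes (camera adjusted p = 0.000334, and adjusted p = 0.205 with an estimated correlation). AT4G25890 fell from 8992 ± 950.5 to 69.4 ± 31.8. In the cell division list 12 of 19 tested genes fell and 1 rose (12 and 1 adjusted within the list). The cell division list averaged -2.09 in log2 relative to the other genes (camera adjusted p = 0.0137, and adjusted p = 0.652 with an estimated correlation). The cell division call was lost in the fit of the compared stages alone (camera adjusted p = 0.330). MCM5 (AT2G07690) fell from 579 ± 82.2 to 19.1 ± 15.9. In the list of fatty acid synthesis 15 of 23 tested genes fell and 0 rose (15 and 0 adjusted within the list, 13 and 1 median-centred). For the fatty acid list the mean was -2.13 relative to the other genes (camera adjusted p = 0.0137, and adjusted p = 0.665 with an estimated correlation). The fatty acid call was lost in the fit of the compared stages alone (camera adjusted p = 0.486) and with DESeq2 (0.0573). The call was lost without mature replicate 1 (adjusted p = 0.151, and 2.11e-06 to 0.486 over other settings at a correlation of 0.01). Among the seed coat markers 7 of 9 tested genes fell and 1 rose (7 and 1 adjusted within the list, 6 and 1 median-centred). Members of the seed coat list averaged -3.52 relative to the other genes (camera adjusted p = 0.0230, and adjusted p = 0.158 with an estimated correlation). The seed coat call was lost with DESeq2 (camera adjusted p = 0.0578). Among the endosperm markers 9 of 13 tested genes fell and 1 rose (9 and 1 adjusted within the list, 7 and 1 median-centred, camera adjusted p = 0.151).

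In the auxin list 9 of 16 tested genes fell and 2 rose (9 and 2 adjusted within the list, 8 and 2 median-centred, camera adjusted p = 0.102), and AUX1 (AT2G38120), an auxin importer, fell from 5619 ± 1069.6 to 53.9 ± 38.6. In the embryo patterning list 14 of 32 tested genes fell and 4 rose (14 and 3 adjusted within the list, camera adjusted p = 0.0974), and DRN fell from 1088 ± 28.8 to 3.03 ± 0.137. For DNA methylation 10 of 23 tested genes fell and 5 rose (10 and 5 adjusted within the list, 10 and 7 median-centred, camera adjusted p = 0.575), with DDM1 (AT5G66750) falling from 420.0 ± 39.96 to 6.16 ± 6.503 and the demethylase gene ROS1 (AT2G36490) rising from 65.1 ± 6.62 to 846 ± 48.7. Among the maturation regulators 7 of 17 tested genes rose and 4 fell (7 and 4 adjusted within the list, camera adjusted p = 0.330), and DOG1 rose from 9.82 ± 11.1 to 1415 ± 194. By size of change, the cysteine protease gene AT4G11310 (chromosome 4, 6883513 to 6885517) rose from 3.18 ± 1.76 to 152899.5 ± 33903 (log2 change 14.38, SE 0.88, adjusted p = 4.10e-09, limma). LTI65 (AT5G52300), an abscisic acid response gene, had 0 reads in zygote and 11243 ± 2796 in mature libraries, at least 3067-fold higher. PIP5K1 (AT1G21980) of phosphoinositide synthesis (chromosome 1, 7734661 to 7738772) fell from 84286 ± 11652 to 2.93 ± 4.15 (log2 change -13.70, SE 0.81, adjusted p = 3.06e-09, limma). The lipid transfer protein gene LTP6 (AT3G08770) fell from 51515 ± 13595 to 6.94 ± 5.40, and GRP5 (AT3G20470), a glycine-rich protein gene, fell from 50652 ± 5049 to 2.74 ± 1.66. MLP43 (AT1G70890) fell from 24489 ± 4126 to 2 reads, a ratio of 19843 (5493 to 163852).

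From zygote to mature 12228 genes passed the test, 5550 up and 6678 down, against 6615 up and 5809 down with median-centred values, and the median log2 change of all genes was -0.16. No single library moved this count by more than 1.5 times when left out.

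**Figure D2:**
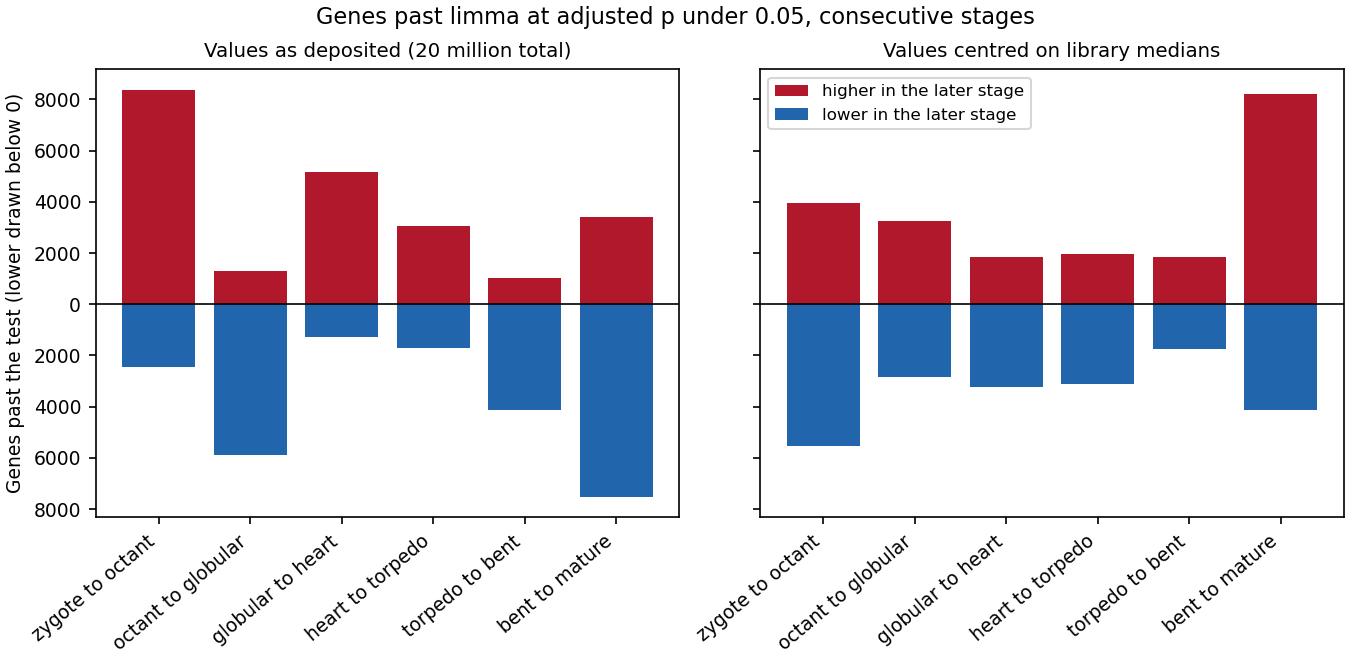
Number of genes past limma at an adjusted p under 0.05 for each pair of consecutive stages (n = 2 libraries per stage), higher in the later stage drawn above 0 and lower drawn below, on the deposited scale (left) and with median-centred values (right). From zygote to octant 8381 genes rose and 2458 fell on the deposited scale, against 3966 and 5519 with median-centred values.

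**Figure D3:**
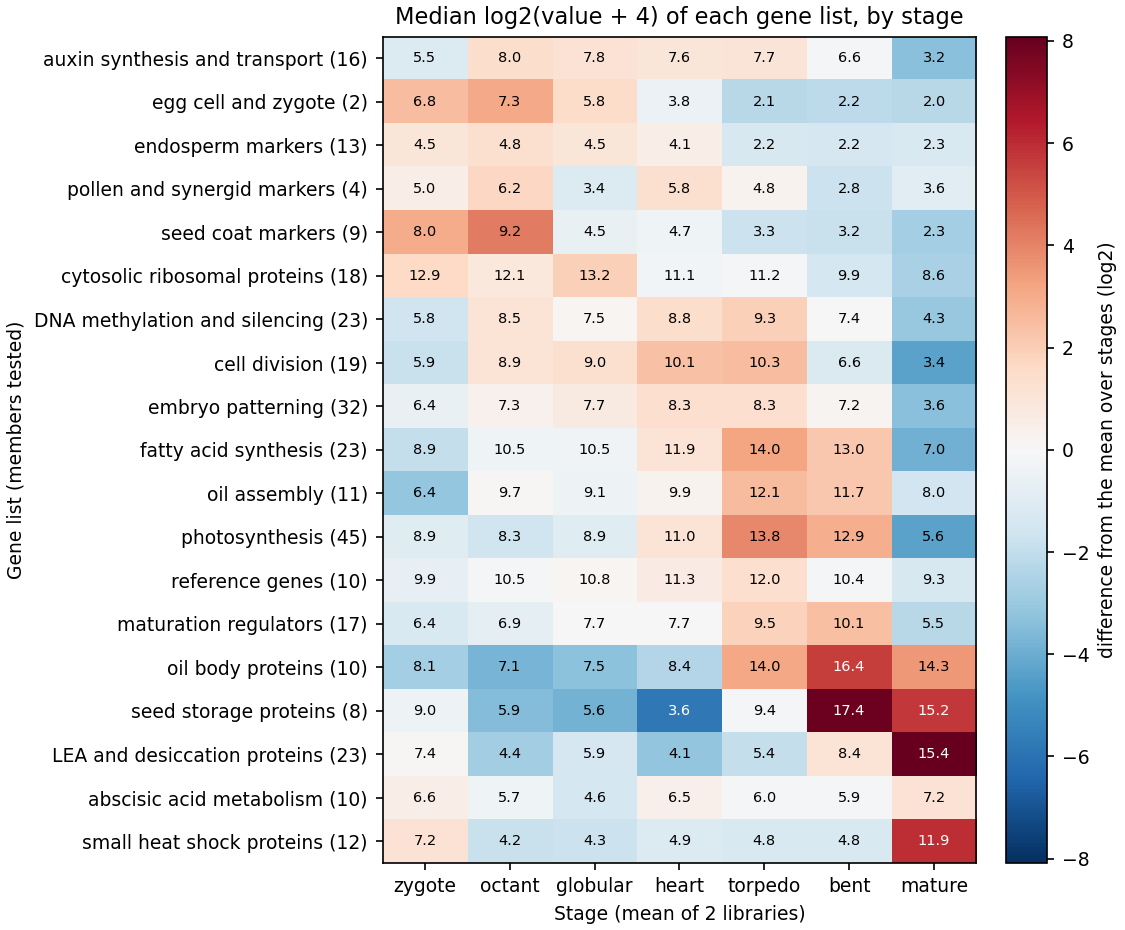
Median log2(value + 4) of the tested members of each gene list at each stage (mean of 2 libraries, deposited scale), with colour for the difference from the list's mean over stages. Seed storage and oil body proteins stood highest at bent, and LEA and small heat shock proteins at the mature stage.

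Each of the 18193 genes that differed among stages was placed at the stage of its highest mean. Photosynthesis genes peaked at torpedo (42 of 45, adjusted p = 1.21e-18 by one-sided Fisher's exact test), as did genes of fatty acid synthesis (21 of 23, adjusted p = 8.07e-09) and cell division (14 of 19, adjusted p = 0.000621). Storage proteins peaked at bent (7 of 8, Fisher's exact adjusted p = 8.21e-06), with oil body proteins (6 of 10, adjusted p = 0.00121) and maturation regulators (6 of 17, adjusted p = 0.0369). LEA proteins (22 of 23, Fisher's exact adjusted p = 2.62e-16) and small heat shock proteins (11 of 11, adjusted p = 1.51e-08) peaked at the mature stage, and cytosolic ribosomal proteins at globular (7 of 18, adjusted p = 0.000590). The other 124 of 133 tests did not pass, and all take a list's genes as independent, so p may be too small. With median-centred values the peaks of storage proteins and maturation regulators no longer passed, and by the lower of the 2 libraries that of the maturation regulators did not. By that lower library patterning genes passed at heart (Fisher's exact adjusted p = 0.0321) and oil assembly genes at bent (0.0201). With median-centred values DNA methylation genes passed at heart (Fisher's exact adjusted p = 0.00409), patterning genes at globular (0.00671) and heart (0.0240), and oil assembly genes at bent (0.00658). In stage order, genes peaking numbered 2459, 3400, 994, 2202, 4951, 1609 and 2578, or 3952, 1764, 2124, 1408, 1718, 1920 and 5307 with median-centred values.

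**Figure D4:**
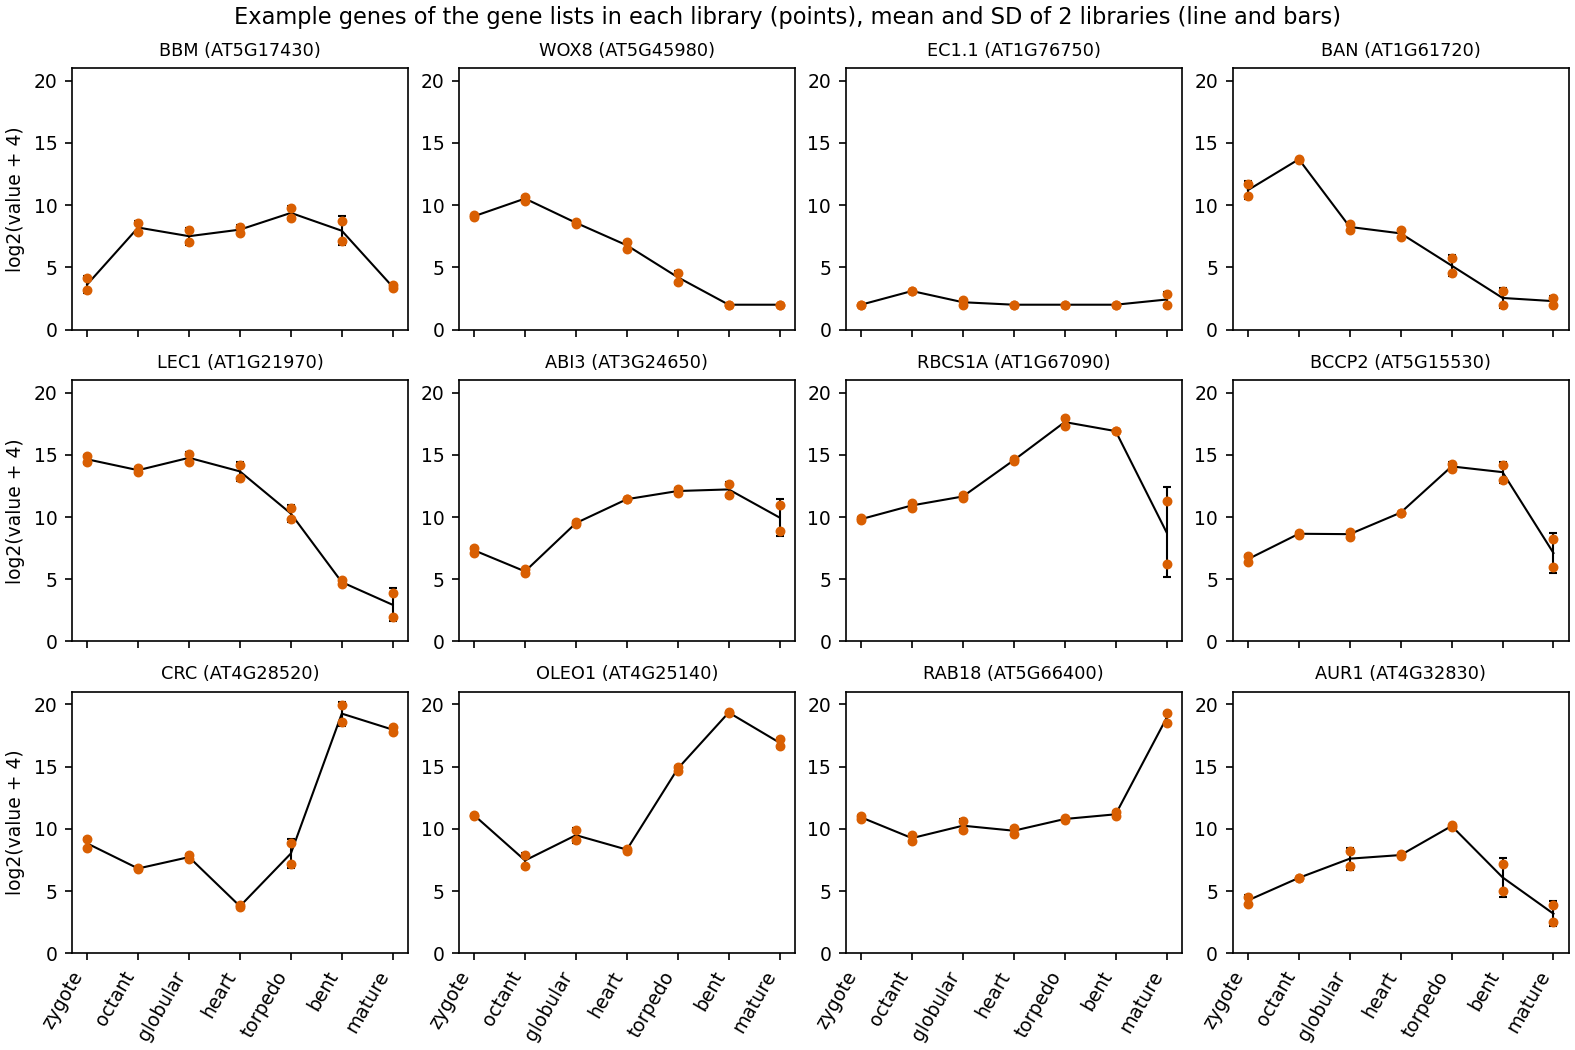
Values of 12 example genes as log2(value + 4) in each library against stage, with points for libraries, a line for the mean and bars for the SD of 2 libraries. CRC and OLEO1 stood highest at bent, RAB18 at the mature stage and LEC1 at zygote and globular.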

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

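No tests were run on the following result, which was noticed after the values were seen. Entries without a gene identifier, which no comparison uses, held 9.15% to 26.3% of the total signal of a library, with the highest share in bent replicate 2. This was picked out because it is signal above what a count of 0 allows in a part of the table that the comparisons leave aside. The last 5 of these 103 entries stand where HTSeq writes its summary lines, and the first of them held up to 16.99% of a library and the last up to 16.6%. The other 98 together held at most 0.502%. What each entry stands for is not given in the sources used here, and no biological explanation was tested.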

How the results depend on the processing

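Median-centring was chosen after the data were seen. All 80 changes of genes named by rule kept their direction and passed under every alternative, except in the fit of the compared stages alone, where 10 of torpedo to bent no longer passed. Of the 54 list calls, 51 to 54 passed with 1 library left out, 54 with a pseudocount of 16, equal totals or array weights, 52 with no or a stricter filter, 51 with a pseudocount of 1, upper-quartile scaling, median-centring or edgeR, 48 with DESeq2 or quantile normalization, and 44 in the fit of the compared stages alone. With the estimated correlation of camera 9 of 133 list tests passed, and 84 passed fry, which asks only whether a list's genes move one way. Of the 54 calls fry kept 47. It lost those of photosynthesis from zygote to octant (fry adjusted p = 0.819) and globular to heart (0.0591), of fatty acid synthesis from octant to globular (0.879) and heart to torpedo (0.0617), and from octant to globular of maturation regulators (0.730), cell division (0.819) and photosynthesis (0.909), the last up by camera with a mean of 0.588 relative to the other genes and down by fry. From bent to mature BEL1 (AT5G41410) went from -1.31 to 0.0762 and EPR1 (AT2G27380) from -1.27 to 0.11 in log2 after median-centring. Of list member changes past the test, median-centring reversed 9 and lost 219, and DESeq2 reversed 3 and lost 193. Without mature replicate 1 these were 1 and 71. The fit of compared stages alone lost 389 and kept 705. It gave 3794 genes for octant to globular, 897 for globular to heart and 0 for torpedo to bent. The torpedo to bent count was 3351 with upper-quartile scaling and 3202 with edgeR. With 1 library left out the counts ranged from 8251 to 11096 for zygote to octant, 4463 to 7517 for octant to globular, 3886 to 6819 for globular to heart, 2554 to 5140 for heart to torpedo and 2515 to 5493 for torpedo to bent. They ranged from 9108 to 11210 for bent to mature, 10549 to 12399 for zygote to mature and 17792 to 18206 for the F test. The range of genes detected between stages, 3451 at a value of 10, was 1684 at 1 and 3727.5 at 50. For the other shifts the cause was not tested. With the replicate number as a block 10854 genes passed from zygote to octant, no count moved by more than 1.5 times, and all 80 rule changes and 54 list calls passed. As a pairing check, correlations of library deviations between 21 pairs of stages ran from -0.111 to 0.299, with 3 over 0.1, all among globular, torpedo and bent, and what replicates of the same number share is not given in the sources used here.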

Other observations

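The tests on scaling, depth, reads outside named genes, carry-over from the mature stage, the mature stage as only source and the bent stage as source of LEA RNAs were chosen after the result was seen. The genes of this paragraph and the next were also chosen after their values were seen. The most abundant RNAs changed from stage to stage (n = 2, share of the library). In zygote libraries RPS10B (AT5G41520), a ribosomal protein gene, held 1.35% ± 0.288. In octant libraries GRP7 (AT2G21660), an RNA-binding protein gene, held 3.35% ± 0.654 and the nucleolin gene NUC-L1 (AT1G48920) held 1.46% ± 1.13. The glycine-rich protein gene AT3G24250 held 6.51% ± 1.65 at globular. At heart the acidic ribosomal protein gene AT2G27710 held 1.96% ± 1.52, and at torpedo RBCS1A (AT1G67090) of Rubisco held 1.03% ± 0.300. At bent CRC held 3.50% ± 2.19 and OLEO1 3.34% ± 0.113. At the mature stage RAB18 (AT5G66400), which overlaps another gene, held 2.54% ± 0.883, EM6 1.81% ± 0.328 and LEA76 1.53% ± 0.675.

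Genes at 1000 or more in a stage and at least 10-fold over every other stage numbered 75 of 2510 in zygote, 6 of 3113 in octant, 3 of 2356 in globular and 2 of 3192 in heart. They numbered 1 of 3467 in torpedo, 22 of 2332 in bent and 239 of 2361 in mature embryos. AT5G47350 stood at 70469 ± 8243 in octant and at 2531 in zygote, its next highest stage. AT1G22065 stood at 14658 ± 2596 in zygote and 97.3 in octant, and AT1G17010, an oxygenase family gene, at 44340.1 ± 18792 in mature and 10.3 in zygote. No test was made on these.

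The LEA, storage, oil body and small heat shock lists lay lower in octant than in zygote libraries by camera, a call that with an estimated correlation held only for the oil body list (camera adjusted p = 0.0442, against 0.0996, 0.103 and 0.116 for the LEA, storage and heat shock lists). Scaling was argued against by a LEA log2 mean of -3.25 relative to other genes (median -4.447 if centred). Mature carry-over as the only source was not decided. In both zygote libraries only 6 of 91 abundant mature genes lay below 0.1 of a prediction from the LEA median. AT4G11310 stood at 3.18 ± 1.76 where 477 was predicted. Carry-over from bent embryos as the source of the LEA RNAs was argued against by 7 LEA genes above bent in both zygote libraries, such as EM1 at 939 ± 280.0 in zygote and 51.2 ± 51.8 in bent. Mature carry-over for part of the signal cannot be told apart from zygote expression. There 6.593% of 91 abundant genes lay below 0.1 of the prediction, between the bounds set. Carry-over from bent met its prediction (2.041% of 49 genes). Zygote-expressed genes also meet it, so the source of storage and oil body RNAs was not decided. Zygote expression or maternal supply stays open as untested.

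Seed coat RNAs were high in zygote and octant and low from globular on. Scaling was argued against, as the list's median change from octant to globular was -3.604 with median-centred values. Seed coat tissue carried in unequal amounts could not be decided, because the median difference between the octant libraries, 0.24, stood at the percentile 70.75 of 10000 random lists matched on level. Equal amounts in both libraries would look the same, so seed coat tissue carried with the young embryos may be a source, and expression in the embryo itself was not tested. How many of the 9 tested markers the embryo itself expresses was not measured apart from these libraries.

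More genes were detected in octant than in zygote libraries, and on the deposited scale most genes were higher there (3966 rose and 5519 fell with median-centred values). Depth was argued against by the 1396 genes by which octant still exceeded zygote at 5403798 reads per library (pooled SD 166), and reads outside named genes by a median change of 0.8337 with equal totals over named genes. Fewer long RNAs in the zygote libraries met the prediction written before the result, with the longest of 4 equal groups of genes by length rising by 1.112 more in log2 than the shortest (1.25 against 0.13), and may be a technical part of the pattern. The same gap was 1.31 from globular to heart, -0.86 from octant to globular and -1.06 from bent to mature. So it is not particular to zygote libraries, and list tests may include it. A wider set of RNAs in the octant embryo stays open as untested.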
